A study of Rattus norvegicus with 24 samples.

How the data were processed

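The deposited files were the Feature Extraction text of each array and a series value table from the authors, and no paper was at hand. Per the file headers the spots were read by Agilent Feature Extraction 10.7.3.1 with the protocol GE1_107_Sep09, and the positions of the 60-mer probes refer to rn4. Per the file headers the deposited processed signal is an intensity, background-subtracted and detrended within the array, with surrogate values for weak spots and no scaling between arrays. The mean signal, the local background and the background-subtracted signal in the deposited files are further intensity values without scaling. The series table is a score: the authors give quantile-normalized values with a median of 0 and an interquartile range of 1 on every array, and it follows the background-subtracted signal. How the authors set that scale is not stated per the submitters' processing notes. The deposited spot marks (well above background, saturated, non-uniform, population outlier) are of the unit other, and were used as marks only.

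Each array held 62976 spots, of which 4259 were controls and 58717 were used. Spots marked as non-uniform or as population outliers (0.652%) were left out, except where all spots of a probe were marked. The processed signal was put on a log2 scale, the 75th percentile of the array was subtracted, and spots were averaged per probe (30367 probes). A probe was kept if it was well above background on at least 6 arrays (21179 probes), and the brightest probe stood for each gene name, which gave 18641 genes out of 26278 names. Current symbols were matched through unversioned transcript accessions for 18004 probes, 13211 of them kept. Other names are those of the array, and a gene whose name changed is given with both at first mention.

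Differences were fitted with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8; drawings with matplotlib 3.10.9), with a mean per diet, moderated two-sided t tests, and Benjamini-Hochberg adjustment over the genes of each of 8 comparisons at 0.05. Those comparisons were the mean copper and mean sucrose differences, their interaction, 4 simple differences, and the diet with both changes against the control diet. The 27 gene lists were tested with limma camera, two-sided against the other genes, with a preset correlation of 0.01 and adjustment over the 27 lists. Comparisons, lists, the 13 fixed genes, the threshold and most other settings were set before the data were examined. Genes were named by a rule. In the mean differences and the diet with both changes, the 10 largest rises and 10 largest falls past the threshold were named, and for the mean differences both underlying differences needed 1 sign. In the other comparisons it was the 5 largest each way, and where none passed the 5 smallest p. Up to 4 members per list with the smallest p were added, with the 13 fixed genes. The rule gave 244 genes in 479 pairs of gene and comparison, and the text describes a selection. Of 91 pairs with other kept probes, 64 had every other probe of the same sign, and 0 named genes were saturated.

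Other settings, chosen beforehand, were normexp background correction (offset 50), quantile normalization, the authors' table (floor 5), no filter, a filter on all arrays, slide or replicate number as a block, the mean of probes, all probes separately, an intensity trend, array weights, a change of at least 1.5 times, leaving out each rat, fitting only both groups compared, and for lists an estimated correlation and fry. The authors' scores cannot be put on a log2 scale as they stand. They were first multiplied by 662 and raised by 80.4, the mean interquartile range and mean median of the background-subtracted signal. This scale is an assumption, and it affects dim genes most. Added after the first results were slide as a random block, the position of the array on its slide as a block, leaving out slide 2, quantile normalization with the slide block, slide 2 alone, the slide block with an estimated correlation, and leaving out 2 rats. Those rats were picked because their inflammatory genes stood apart, and they also stood apart in the most of 108 genes examined. Smaller inflammatory differences without them are therefore in part built in. A check of list members with each rat left out was added while the text was written. Replicate numbers did not pair rats across diets (correlations of -0.29 to 0.36).

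The fit was tested on simulated data, with 200 of 18641 genes changed. For low copper at 10% sucrose it found 22.4, 74.6 and 98.5% of changes of 0.5, 1 and 2 log2 units, with 6 false calls. With slide as a block it found 5.97, 47.8 and 87.9%, with 4 false calls, so a count of 0 with the block leaves moderate changes open. A list of 25 genes shifted by 0.5 was found, and 4 of 100 unchanged lists had p under 0.05. The simulated genes varied independently of each other and without slide differences. These rates of false calls therefore do not carry over to genes that vary together or to slide differences. With 6 rats per diet the number of arrays limits precision, and no rat was measured more than once. No array was left out, and no pair of arrays was identical (0 pairs).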

Results

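Gene expression was measured in the livers of 24 male Wistar rats with one-colour Agilent arrays, 1 array per rat. The rats were 6 months old at the start and ate purified diets for 12 weeks, in a model of fatty liver disease not caused by alcohol. The design crossed copper with sucrose: 6 rats ate low copper (less than 0.3 mg/kg) with 30% sucrose, 6 adequate copper (125 mg/kg, called high copper in the sample titles) with 30% sucrose, 6 low copper with 10% sucrose, and 6 adequate copper with 10% sucrose, the control diet. Starch and dextrin kept the total carbohydrate equal. Levels are given as log2 signal over the 75th percentile of the array, as mean ± SD over 6 rats unless another number is given, and differences as log2 values with the standard error (SE) of the fit. Across arrays the 75th percentile of the signal lay between 433 and 1284, against a local background of 38 to 48, and 59.9 to 73.4% of probes were well above background. The tests covered 18641 genes, each represented by 1 probe.

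The diets were spread unevenly over the 3 slides that held 8 arrays each. Slide 1 held all 6 rats on low copper with 30% sucrose and 2 on adequate copper with 30% sucrose. Slide 2 held the other 4 of that diet and 4 rats on low copper with 10% sucrose, and slide 3 held the remaining 2 and all 6 control rats. Low and adequate copper can therefore be compared within a slide, with 6 against 2 rats on slide 1 at 30% sucrose and with 2 against 6 rats on slide 3 at 10% sucrose. No slide held both sucrose levels at the same copper level, so a sucrose difference with slide as a block rests on a chain of slides. Values from a fit with slide as a block are given beside most results. Where a gene was well above background in 0 of the 6 rats of a diet compared, no size of its difference is given in the comparisons described next, since a level at background has no exact value.

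The first question was what low copper did to the liver, averaged over both sucrose levels. Metallothionein genes, whose proteins bind copper and zinc, had lower mean levels on both low copper diets. Mt1a (now Mt1; probe on chromosome 19 from 11261631, rn4) stood at 4.56 ± 0.43 on low copper with 30% sucrose, 5.90 ± 1.18 on adequate copper with 30% sucrose, 5.48 ± 0.85 on low copper with 10% sucrose and 6.37 ± 0.51 on the control diet. Mt2A (chromosome 19 from 11267834) stood at 2.45 ± 0.14, 3.98 ± 1.66, 3.19 ± 0.99 and 4.04 ± 0.53 in the same order. The mean copper difference was -1.12 for Mt1a (limma, SE 0.31, adjusted p = 0.360) and -1.19 for Mt2A (SE 0.38, adjusted p = 0.364), so neither passed over all genes. With array weights Mt1a did (-0.93, adjusted p = 0.0406, the lowest over 35 alternatives), and Mt2A did not (adjusted p = 0.0544, also its lowest). Those weights were lowest for a low copper rat that shares slide 3 with the control rats, which ties diet closer to slide. Under the slide block the differences were -1.36 and -1.14 (adjusted p = 0.9998 each).

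Within slides, where low and adequate copper met at one sucrose level, both metallothionein genes differed in the same direction. Mt1a was lower by 0.94 on slide 1 and by 1.78 on slide 3, and Mt2A by 0.54 and 1.75. The exact two-sided permutation p over all regroupings within those slides was 0.00128 for each gene, the smallest that these slides can give, and 0.00829 after adjustment over the 13 genes fixed before the data were examined. One rat on adequate copper with 30% sucrose, rat 5, stood far above the rest for both genes, with 8.25 for Mt1a and 7.18 for Mt2A. That rat lies on slide 2 and does not enter the within-slide test.

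**Figure D1:**
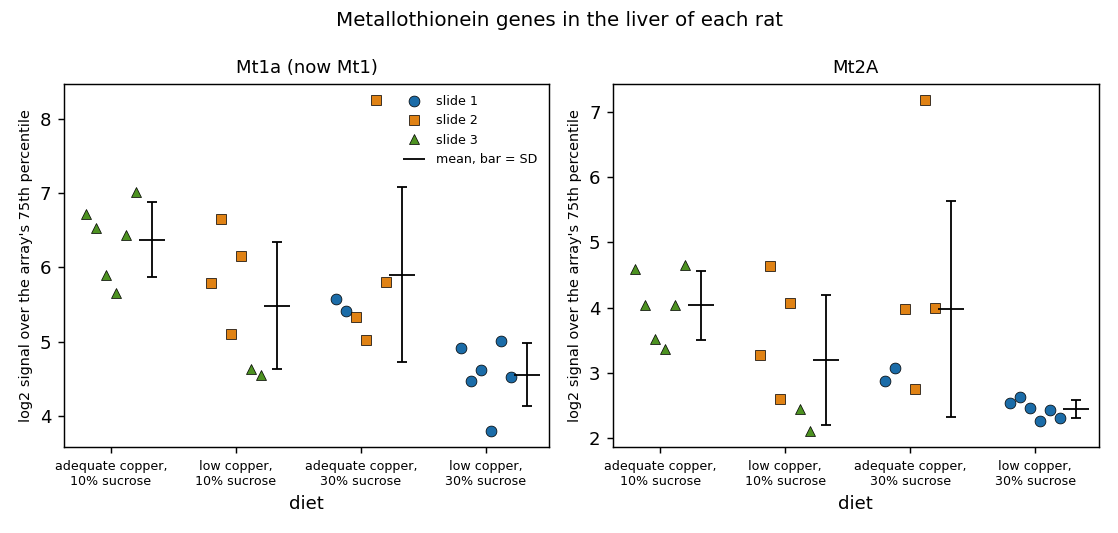
Levels of Mt1a and Mt2A (log2 signal over the 75th percentile of the array, y axis) in each of the 24 rats by diet (x axis), with the mean and SD of each diet and a colour and shape per slide. On low copper with 30% sucrose Mt2A averaged 2.45 ± 0.14, against 4.04 ± 0.53 on the control diet.

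Other genes of copper transport and use had small mean copper differences. The mean copper difference was -0.07 for Cp (ceruloplasmin, the copper-carrying ferroxidase of plasma), -0.07 for Ccs (the copper chaperone of superoxide dismutase), -0.01 for Sod1, 0.10 for Atp7a and -0.02 for Atp7b (copper-exporting pumps), and 0.01 for Slc31a1 (a copper importer). Among lipid and sugar genes fixed beforehand it was 0.56 for Fasn (fatty acid synthase), 0.06 for Scd1 (now Scd), 0.12 for Srebf1, 0.29 for Pklr and 0.09 for Khk (ketohexokinase, which phosphorylates fructose). Cp was higher on adequate copper with 30% sucrose than on the control diet, by 0.79 with 6 of 6 rats above the control mean (SE 0.27, adjusted p = 0.0366; 0.77 with slide as a block), but this call was lost with quantile normalization (adjusted p = 0.0650), without rat 4 (adjusted p = 0.0551), rat 5 (0.111) or rat 6 (0.0510) of that diet and without control rat 2 (0.0641), 5 (0.0820) or 6 (0.0746). The mean copper differences of Cp (0.03), Atp7b (0.0013), Scd (-0.09) and Khk (-0.10) turned sign with slide as a block, and those of Fasn (0.30) and Pklr (0.07) were smaller. For these 11 genes and the mean copper difference the exact within-slide permutation p was 0.259 or above (0.763 or above after adjustment over the 13). The differences do not pass, which leaves changes smaller than the spread between rats open.

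Across all genes, 0 passed for the mean copper difference with limma, while 1640 had an unadjusted p under 0.05 where 932 would be so by chance. After blocking by slide the number was again 0, with 494 at an unadjusted p under 0.05, but with array weights 875 genes passed. The lowest weight (0.417) fell on rat 6 of low copper with 10% sucrose, which lies on slide 3 with the control rats. Giving that rat less weight brings diet and slide closer together, so the 875 may include slide differences. The 5 genes with the smallest p did not pass: Olr1515 (now Or1p1e, an odorant receptor; 1.22, adjusted p = 0.241), Olr50 (now Or52r1; 1.08), Gpr112l (higher, without an exact size), Vom1r6 (a vomeronasal receptor; 0.60) and Olr213 (now Or13n4b; 0.54). On the control diet Or1p1e, Or52r1 and Vom1r6 were well above background in 2 of 6 rats each, and Gpr112l in 0. Without rat 6 of low copper with 10% sucrose 19 genes passed, among them Or1p1e (1.39, adjusted p = 0.000374), Gpr112l (0.0116), Vom1r6 (0.66, 0.0324) and Or52r1 (1.21, 0.0389). That rat is 1 of the 2 of its diet that share slide 3 with the control rats. Leaving it out brings diet and slide closer together, so these 19 cannot be told apart from a slide difference.

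Tested as groups with limma camera, 10 of the 27 fixed gene lists shifted against the other genes with the mean copper difference, and 2 of these calls held with an estimated correlation. With fry 0 lists were called. The iron and heme list was lower: 17 of 21 measured genes lay below 0, with a median of -0.08 (adjusted p = 0.000460, and adjusted p = 0.0347 with an estimated correlation; adjusted p = 0.109 with slide as a block). Its members included Hamp, the iron hormone hepcidin (-0.34), Tfrc, the transferrin receptor (-0.27), Id1 (-0.57) and Fth1, the ferritin heavy chain (-0.09), and none passed alone. The copper handling list was lower too, with 16 of 22 genes below 0 and a median of -0.05 (adjusted p = 0.00317, adjusted p = 0.0289 with an estimated correlation, adjusted p = 0.151 with slide as a block). In it Steap4, a metalloreductase, stood at -0.42 and Steap2 at 0.35. Adjusted over the list alone, 1 copper handling gene and 0 iron genes passed, and 0 of either passed over all genes (limma).

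Interferon response genes were higher as a group on low copper, with 20 of 25 above 0 and a median of 0.14 (adjusted p = 0.00733). Oas1a stood at 0.87, Usp18 at 0.75 and Ifi44 at 0.30, none past the threshold alone. The call was kept with slide as a block (median 0.14, adjusted p = 0.0126), but adjusted p = 0.749 with an estimated correlation (0.828 with both), and adjusted p = 0.349 without rat 5 of adequate copper with 30% sucrose and rat 2 of low copper with 10% sucrose, the pair of rats that stood apart in the most genes. The range of adjusted p over these alternatives was 0.0126 to 0.828. The lipoprotein and lipid transport list was lower, with a median of -0.06 over 27 genes (adjusted p = 0.00317; adjusted p = 0.231 with an estimated correlation). In this list Scarb1, the receptor for high density lipoprotein, stood at -0.33 (SE 0.10, adjusted p = 0.360). Fibrosis and stellate cell genes (33 measured, median -0.09, adjusted p = 0.00470; adjusted p = 0.749 with an estimated correlation) were lower as a group. The other 5 calls, in cholesterol synthesis, fatty acid oxidation, inflammatory, acute phase and macrophage genes, also ran towards lower levels and were all lost with an estimated correlation (adjusted p of 0.749 to 0.770). The inflammatory median went from -0.07 to 0.03 with slide as a block, and its test turned to higher (adjusted p = 0.444).

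The next question was what 30% sucrose did, averaged over both copper levels. No gene passed with limma (0 of 18641, with 2013 at an unadjusted p under 0.05), and 0 passed with slide as a block (1110). The 5 smallest p belonged to Wdr96 (now Cfap43; 0.76), Ttc39a (0.50), Mmp25 (0.52), Lmln (higher, with 0 of 6 control rats above background) and Blnk (an adaptor of B cell signalling; 0.80), each with an adjusted p of 0.246. The lipogenic genes fixed beforehand had mean sucrose differences of 0.73 for Fasn (SE 0.36, adjusted p = 0.476), 0.24 for Pklr, 0.18 for Srebf1, 0.12 for Scd and 0.05 for Khk. For Blnk the difference was 0.00 with slide as a block, and for Fasn 0.21.

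As groups, 7 lists shifted with the mean sucrose difference, and none of the 7 calls held with an estimated correlation. Fatty acid oxidation and PPAR alpha targets were lower, with 29 of 31 genes below 0 and a median of -0.21 (adjusted p = 2.2e-10; adjusted p = 0.449 with an estimated correlation). Members included Acot12, a thioesterase (-0.36), Plin2, which coats lipid droplets (-0.40), and Angptl4 (-0.36). Cholesterol synthesis genes were higher, with 22 of 25 above 0 and a median of 0.21 (adjusted p = 0.00449; adjusted p = 0.780 with an estimated correlation), among them Acat3 (now Acat2; 0.47). Hepatocyte genes were lower in 21 of 22 cases, with a median of -0.09 (adjusted p = 0.000334; adjusted p = 0.449 with an estimated correlation), among them Glul (glutamine synthetase; -0.38) and Hpd (-0.27). Red blood cell genes were higher (10 of 11, median 0.68, adjusted p = 0.0206; adjusted p = 0.589 with an estimated correlation), with the haemoglobin genes Hba-a2 (now Hba-a1) at 0.70 and Hbb-b1 at 0.81. Without the pair of rats that stood apart the call of the red blood cell list was lost (median 0.56, adjusted p = 0.0688). With slide as a block the fatty acid oxidation median was -0.11 and its test against other genes turned to higher (adjusted p = 0.905), while the cholesterol median was 0.12 (adjusted p = 0.000600, but 0.843 with the block and an estimated correlation).

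At adequate copper, single inflammatory genes and neutrophil genes were higher on 30% sucrose than on the control diet in the fit without a slide term. The diets compared share no slide, so a slide difference would enter all values without a block in this comparison. Cxcl1 (chromosome 14 from 18690468), a chemokine that attracts neutrophils, stood at 2.32 ± 1.05 against -1.40 ± 1.69, a rise of 3.71 (SE 1.05, adjusted p = 0.0147). S100a8 rose by 2.94 (SE 0.85, adjusted p = 0.0163) and S100a9 by 2.75 (SE 0.80, adjusted p = 0.0172), which together form calprotectin, a protein of neutrophils. All 6 rats on 30% sucrose lay above the control mean for each of the 3 genes. Under the slide block the differences were 4.56, 3.26 and 2.90, and none of them passed. Rat 5 of this diet stood apart from its group in 7 of 108 genes examined. Leaving it out together with rat 2 of low copper with 10% sucrose left 3.42 for Cxcl1 (adjusted p = 0.0251), 2.01 for S100a8 (0.00680) and 1.93 for S100a9 (0.00758).

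Further members of the immune lists rose in the same comparison. These, and members of other lists given below for this diet, had been named by the rule in another comparison, and this comparison was chosen for them after their values were seen. Members that lost their call without 1 rat are left unnamed unless the rat is given. Cxcr2, the receptor for Cxcl1, rose by 1.90 (SE 0.32, adjusted p = 0.000973), Csf3r, the receptor for the granulocyte growth factor, by 1.54 (adjusted p = 0.00110), Lbp, which binds bacterial lipopolysaccharide, by 1.48 (adjusted p = 0.0202) and Socs3, which dampens cytokine signals, by 0.67 (adjusted p = 0.0166), each in 6 of 6 rats. Without rat 5 of adequate copper with 30% sucrose Lbp (1.11, adjusted p = 0.0611) and Socs3 (0.55, adjusted p = 0.0523) no longer passed. As a group, 5 of 8 neutrophil genes passed and 6 when adjusted over the list alone (median 1.25, adjusted p = 0.00623; adjusted p = 0.385 with an estimated correlation). Of 25 inflammatory genes 4 passed, no larger a share than the 3426 of 18641 genes called higher in all, and 4 when adjusted over the list alone (median 0.60, adjusted p = 0.0381; adjusted p = 0.632 with an estimated correlation). After blocking by slide the medians were 0.42 for neutrophil and 0.49 for inflammatory genes, and the difference for Csf3r was 0.19.

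**Figure D2:**
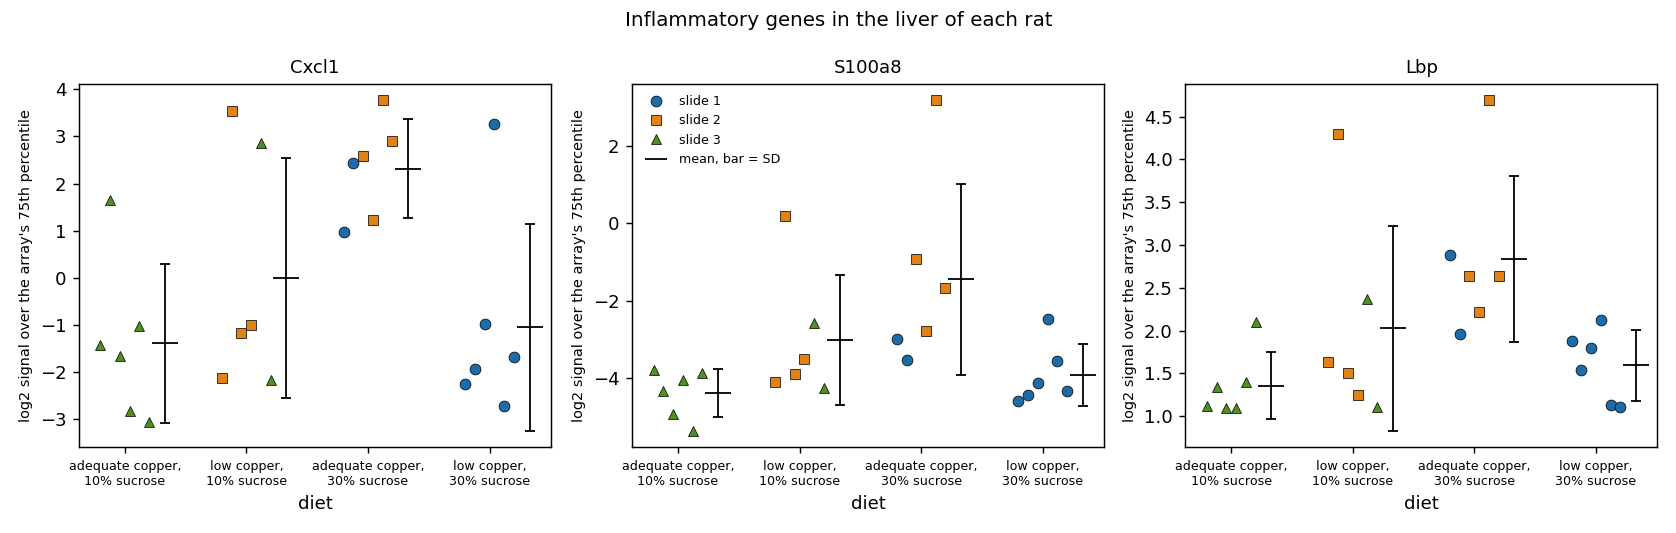
Levels of inflammatory genes (log2 signal over the 75th percentile of the array, y axis) in each rat by diet (x axis), with the mean and SD of each diet and a colour and shape per slide. Cxcl1 averaged 2.32 ± 1.05 on adequate copper with 30% sucrose and -1.40 ± 1.69 on the control diet.

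T, B and NK cell genes rose with 30% sucrose at adequate copper only without a slide term. Of 16 measured, 6 passed, and 6 when adjusted over the list alone (median 0.49, adjusted p = 0.0284; adjusted p = 0.632 with an estimated correlation), among them Cd3d by 1.04, Lck by 1.12 and Cd8b by 0.75, each in 6 of 6 rats. With slide as a block the median of the list was -0.29 and Lck stood at -0.07. Red blood cell genes were higher too, with 4 of 11 past the threshold and 7 when adjusted over the list alone (median 1.02, adjusted p = 0.0396; adjusted p = 0.560 with an estimated correlation). Ahsp, the chaperone of alpha haemoglobin, rose by 1.29 in 6 of 6 rats (adjusted p = 0.0147). The list kept a median of 0.92 with slide as a block, and without the pair of rats named above its adjusted p was 0.134.

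In this comparison the cholesterol synthesis list was called higher and the fatty acid oxidation list lower, and both calls were lost with an estimated correlation. Of the cholesterol synthesis genes 6 of 25 passed over all genes, beside 3426 of all 18641 called higher, and 8 when adjusted over the list alone (median 0.46, adjusted p = 0.0196; adjusted p = 0.632 with an estimated correlation). Under the slide block the median of the list was 0.43 (adjusted p = 8.5e-06, but 0.460 with an estimated correlation as well). Of the fatty acid oxidation genes 4 of 31 fell past the threshold over all genes, and 2 when adjusted over the list alone (median -0.35, adjusted p = 1.6e-06; adjusted p = 0.385 with an estimated correlation). Acot12 fell by 0.77 in 6 of 6 rats (SE 0.15, adjusted p = 0.00192; -0.79 with slide as a block), and the median of the list with slide as a block was -0.19 (adjusted p = 0.0385, and 0.670 with an estimated correlation as well). The list of fatty acid and triglyceride synthesis was not called (median -0.04, adjusted p = 0.0683), with Fasn at 0.54.

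Genes of hepatocyte function were lower on 30% sucrose at adequate copper. Hal, the first enzyme of histidine breakdown, fell by 0.67 (adjusted p = 0.0205) and Rgn, regucalcin, by 0.52 (adjusted p = 0.00841), each in 6 of 6 rats, and 3 of 22 hepatocyte genes passed over all genes and over the list alone (median -0.21, adjusted p = 0.000261; adjusted p = 0.385 with an estimated correlation). In the bile acid list 2 of 16 passed in both ways (median -0.18, adjusted p = 0.00436; adjusted p = 0.385 with an estimated correlation): Baat, which joins bile acids to amino acids, fell by 0.40 (adjusted p = 0.00676) and Cyp8b1, the enzyme of cholic acid synthesis, by 1.35 (adjusted p = 0.0104), in 6 of 6 rats each. Respiratory chain genes were slightly lower, with 3 of 34 past the threshold over all genes and 0 over the list alone (limma; median -0.17, adjusted p = 5.6e-06; adjusted p = 0.49 with an estimated correlation). Drug metabolism genes had 1 of 25 past the threshold (median -0.34, adjusted p = 0.000697; adjusted p = 0.385 with an estimated correlation). After blocking by slide the medians of these 4 lists were -0.13, -0.21, -0.19 and -0.46. Lipoprotein genes (median -0.06, adjusted p = 0.0381) and oxidative stress genes (24 measured, median -0.15, adjusted p = 0.0472) lost their calls with an estimated correlation (adjusted p = 0.388 and adjusted p = 0.560).

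Several lists were not called in this comparison. The median was 0.36 for 14 bile duct genes (adjusted p = 0.334), 0.63 for 6 pancreas and adipose genes (adjusted p = 0.385), 0.06 for 16 circadian genes (adjusted p = 0.602) and 0.60 for 18 immediate early genes (adjusted p = 0.0683). For 14 endothelial genes it was 0.04 and for 20 genes of the unfolded protein response 0.02, while their tests against other genes pointed lower (adjusted p = 0.490 and adjusted p = 0.626). Without the pair of rats that stood apart the immediate early list was called (median 0.69, adjusted p = 0.0395). Outside called lists Car3, a carbonic anhydrase, fell by 1.56 in 5 of 6 (adjusted p = 0.00942).

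In all, 3888 genes passed for 30% sucrose at adequate copper with limma, 3426 higher and 462 lower. With quantile normalization the split was 1691 higher and 816 lower. Among the largest changes by the rule were also a rise of V1rd15, a vomeronasal receptor (2.61, adjusted p = 0.00132; well above background in 1 of 6 control rats, and 0.00 with slide as a block), and a fall of Mmd2 (-3.44, SE 1.02, adjusted p = 0.0187; -3.39 with slide as a block), each in 6 of 6 rats. With slide as a block 0 genes passed (758 at an unadjusted p under 0.05), and 2723 of the 3888 kept their sign. The 3888 were chosen on the same rats, so the kept signs are not independent evidence.

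Low copper at 10% sucrose, against the control diet, gave 3469 genes, 3358 higher and 111 lower. With quantile normalization the split was 1677 higher and 381 lower. The largest rises fell on genes with weak signals: V1rd15 by 2.84 (adjusted p = 0.000898; 1.05 with slide as a block), Or1p1e by 2.71 (SE 0.31, adjusted p = 0.000181; 1.95 with the block) and Vom1r21 by 2.71 (adjusted p = 0.000816; 1.55 with the block), each in 6 of 6 rats. On the control diet V1rd15 was well above background in 1 of 6 rats and Or1p1e and Vom1r21 in 2 each, so these sizes are rough. Col6a3, a chain of type VI collagen (adjusted p = 0.00101), and Olr398 (now Or1j22; adjusted p = 0.00139) were higher too, in 6 of 6 rats, without an exact size. Among falls, Pex26, a protein of peroxisome assembly, dropped by 1.06 (SE 0.29, adjusted p = 0.0122; -0.81 with slide as a block) and Tcf21, a transcription factor of mesenchymal cells, by 0.83 (SE 0.24, adjusted p = 0.0154; -1.19 with the block), each in 6 of 6 rats. Mt1a stood at -0.89 (SE 0.43, adjusted p = 0.181, lower in 5 of 6 rats) and Mt2A at -0.84 (SE 0.54, adjusted p = 0.349, lower in 4 of 6). Mt1a passed without rat 5 of adequate copper with 30% sucrose (-0.89, adjusted p = 0.0482), and both passed without the pair of rats that stood apart (-1.13 each, adjusted p = 0.0116 and adjusted p = 0.0171). Over the alternatives the adjusted p ran from 0.0116 to 0.577 for Mt1a and from 0.0171 to 0.651 for Mt2A.

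By group, 10 lists shifted with low copper at 10% sucrose, none of them with an estimated correlation. Counts of higher list members stand beside 3358 of all 18641 genes called higher. T, B and NK cell genes were higher (5 of 16 over all genes and over the list alone, median 0.52, adjusted p = 0.0156; adjusted p = 0.667 with an estimated correlation), with Cd3d up by 0.98, Lck by 1.10 and Cd8b by 0.90 in 6 of 6 rats each. Under the slide block the median was -0.13, and without the pair of rats that stood apart it was 0.27 (adjusted p = 0.109). Neutrophil genes were higher (2 of 8 over all genes and over the list alone, median 1.04, adjusted p = 0.0301; adjusted p = 0.561 with an estimated correlation), with Csf3r up by 1.33 and Cxcr2 by 1.75, and a median of 0.66 without that pair. Acta2, smooth muscle actin, rose by 0.75 and Tgfb2 by 1.45, each in 6 of 6 rats. In all 3 of 33 fibrosis genes passed the threshold, a smaller share than over all genes. The list itself was not called (median 0.01, mean 0.10, with the test pointing lower, adjusted p = 0.440). Without that pair of rats the fibrosis list was called, with a median of -0.11 (adjusted p = 0.0353). Fatty acid oxidation genes were lower (median -0.19, adjusted p = 0.000201; adjusted p = 0.561 with an estimated correlation; median -0.07 without that pair), with Acot12 down by 0.51 in 6 of 6 rats (adjusted p = 0.0214), a call lost without rat 2 of either diet (adjusted p = 0.0567 without the control rat, 0.0527 without the other). Cd3d, Lck, Cd8b, Csf3r, Cxcr2, Acta2, Tgfb2 and Acot12 were named by the rule in another comparison, and were given here after their values were seen.

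After blocking by slide 0 genes passed for low copper at 10% sucrose (limma; 1252 at an unadjusted p under 0.05). The median of the 3358 higher genes was 0.97 without a slide term and 0.43 with one, and 3307 of the 3469 kept their sign. These genes were chosen without a slide term on the same rats, so the kept signs and the 0.43 are not independent evidence. Within the low copper, 10% sucrose diet itself, the 4 rats on slide 2 differed from the 2 on slide 3 in 1425 genes, 1407 of them higher on slide 2. On slide 2 alone, where that diet meets adequate copper with 30% sucrose, 0 genes passed with 4 rats each (limma; 1413 at an unadjusted p under 0.05).

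The interaction asked whether the effect of low copper differed between 30% and 10% sucrose, and 3884 genes passed with limma, 361 positive and 3523 negative. With quantile normalization the split was 793 positive and 1779 negative. Both diets on slide 2 enter the interaction with a negative sign, so a slide 2 effect would enter these counts too. With slide as a block 10 genes passed. Negative values included inflammatory genes. Cxcl1 stood at -4.76 (SE 1.49, adjusted p = 0.0255), S100a8 at -3.83 (SE 1.20, adjusted p = 0.0256) and S100a9 at -3.64 (SE 1.13, adjusted p = 0.0249), since each was lower in low than in adequate copper at 30% sucrose and higher at 10% sucrose. Vom1r21 (-3.69, adjusted p = 0.000954; above background in 2 of 6 control rats) showed the same crossing, as did Col6a3 (adjusted p = 0.000954) without an exact size. Slide-blocked values were -4.51 for Cxcl1, -1.63 for S100a8, -1.74 for S100a9 and -2.16 for Vom1r21. Positive values included Cox6c-ps1 (1.60, adjusted p = 0.0238; 0.44 with the block). Without the pair of rats that stood apart Cxcl1 no longer passed (-3.76, adjusted p = 0.0839), while S100a8 (-2.27, adjusted p = 0.0233) and S100a9 (-2.16, adjusted p = 0.0262) did. With quantile normalization these 2 did not pass (adjusted p = 0.0617 and adjusted p = 0.0516).

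Of the 27 lists 11 were called in the interaction, none with an estimated correlation. Neutrophil genes had 5 of 8 members past the threshold and 6 over the list alone, all negative (median -1.56, adjusted p = 0.00291; adjusted p = 0.441 with an estimated correlation). T, B and NK cell genes had 7 of 16, and 8 over the list alone, all negative (median -0.96, adjusted p = 0.00118; adjusted p = 0.496 with an estimated correlation). Respiratory chain genes went the other way (29 of 34 positive, median 0.27, adjusted p = 1.3e-06; adjusted p = 0.496 with an estimated correlation), as did drug metabolism genes (21 of 25 positive, median 0.46, adjusted p = 0.000832; adjusted p = 0.441 with an estimated correlation). With slide as a block the medians of these 4 lists were -0.95, -0.16, 0.04 and 0.38, and 10 genes passed, all negative. Of the 3884 genes, 3849 kept their sign with the block, but they were chosen on the same rats, so this is not independent evidence.

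At 30% sucrose alone, low against adequate copper gave 0 genes with limma (1839 at an unadjusted p under 0.05), and 20 genes, all lower, with slide as a block. The 5 smallest p belonged to Sh2d4b and Spns3 (each lower, at background in all rats on low copper), Prm3, a protamine (-0.71), Arhgap23 (-0.79) and Rgn (0.61), with adjusted p of 0.261 to 0.352. Of these Spns3 passed with slide as a block (adjusted p = 0.0272). Mt1a stood at -1.34 (SE 0.43, adjusted p = 0.463) and Mt2A at -1.53 (SE 0.54, adjusted p = 0.463). Without rat 5 of adequate copper with 30% sucrose they were -0.87 and -0.89.

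In that comparison 15 lists shifted, none with an estimated correlation. Fatty acid and triglyceride synthesis genes were higher on low copper (18 of 22 above 0, median 0.27, adjusted p = 6.9e-05; adjusted p = 0.366 with an estimated correlation), with Pklr at 0.71, Fasn at 0.75 and Srebf1 at 0.41, none of them past the threshold. Fructose and glucose genes were higher (17 of 25, median 0.15, adjusted p = 0.00262; adjusted p = 0.366 with an estimated correlation), and oxidative stress genes too (18 of 24, median 0.19, adjusted p = 6.9e-05; adjusted p = 0.366 with an estimated correlation). The lower lists included macrophages (20 of 21 below 0, median -0.45, adjusted p = 0.000367; adjusted p = 0.490 with an estimated correlation), acute phase genes (20 of 23 below 0, median -0.28, adjusted p = 0.00168; adjusted p = 0.490 with an estimated correlation) and immediate early genes (17 of 18 below 0, median -0.48, adjusted p = 0.00207; adjusted p = 0.382 with an estimated correlation). Under the slide block the medians of these 6 lists were 0.01, -0.07, 0.09, -0.24, -0.35 and -0.20. Of the 6, the acute phase list alone was called with the block (adjusted p = 0.0454; 0.909 with an estimated correlation as well), and without the pair of rats that stood apart its adjusted p was 0.0527. Inflammatory genes (median -0.45, adjusted p = 6.9e-05; adjusted p = 0.366 with an estimated correlation) and fibrosis genes (median -0.15, adjusted p = 0.0188; adjusted p = 0.551 with an estimated correlation) were also called lower, but both tests turned to higher with the block, with medians of -0.13 (adjusted p = 0.734) and 0.13 (adjusted p = 0.0464; 0.909 with an estimated correlation as well).

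For 30% against 10% sucrose at low copper 0 genes passed with limma (1786 at an unadjusted p under 0.05), and 6, all lower, with slide as a block. The smallest p belonged to Trpv4, a calcium channel (-1.09), Nudcd2 (0.59), Arrdc4 (-1.01), and Ctsll3 and Foxd3 (each lower, at background in all rats on 30% sucrose), with adjusted p of 0.275 to 0.350. Without rat 6 of low copper with 10% sucrose 41 genes passed, among them these 5 (adjusted p of 0.0133 for Trpv4, 0.0483 for Nudcd2, 0.0383 for Ctsll3, 0.0149 for Arrdc4 and 0.0391 for Foxd3), and without rat 5 of that diet 2 genes passed, 1 of them Ctsll3 (0.0238). Rats 5 and 6 are the 2 of that diet on slide 3, so leaving out either brings diet and slide closer together. Of the lists, 8 shifted, none with an estimated correlation. Fatty acid and triglyceride synthesis genes were higher (18 of 22, median 0.19, adjusted p = 0.000230; adjusted p = 0.708 with an estimated correlation), and cell cycle genes too (15 of 22, median 0.07, adjusted p = 0.0423; adjusted p = 0.708 with an estimated correlation). T, B and NK cell genes were lower in all 16 cases (median -0.55, adjusted p = 8.2e-05; adjusted p = 0.708 with an estimated correlation). After blocking by slide the medians were -0.11, 0.09 and -0.59.

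The diet with both changes, low copper with 30% sucrose, was set against the control diet last. Mt1a fell by 1.82 (SE 0.43, adjusted p = 0.0380), with all 6 rats below every control rat, and Mt2A stood at -1.59 (SE 0.54, adjusted p = 0.113), again with all 6 rats below. Mt2A passed without rat 5 of adequate copper with 30% sucrose (adjusted p = 0.0357), without the pair of rats that stood apart (0.0250), with array weights (0.0173) and with only both groups fitted (0.00226). Neither gene passed with normexp (0.2075 for Mt1a, 0.333 for Mt2A), quantile normalization (0.0809 and 0.176) or the authors' table (0.0953 and 0.176). The diets compared here share no slide. With slide as a block the values were -2.54 for Mt1a (adjusted p = 0.878) and -1.46 for Mt2A (adjusted p = 0.998). Agxt, a peroxisomal enzyme that clears glyoxylate, fell by 0.70 (SE 0.16, adjusted p = 0.0347; -0.18 with the block), Plin5, a lipid droplet protein, by 0.90 (SE 0.22, adjusted p = 0.0428; -0.89 with the block), Gde1 by 0.66 (adjusted p = 0.0468; -0.22 with the block) and Rtn1 by 0.94 (adjusted p = 0.0420; -0.14 with the block), each in 6 of 6 rats. V1rd15 was higher by 2.40 (adjusted p = 0.0265), but its sign turned with the block (-0.04). Or1p1e was higher by 1.88 (SE 0.31, adjusted p = 0.0152; 1.04 with the block), RT1-M5 by 1.85 (adjusted p = 0.0265; 0.58 with the block) and Pfkfb3, which makes the activator of phosphofructokinase, by 0.84 (adjusted p = 0.0366; 0.21 with the block), each in 6 of 6 rats. On the control diet V1rd15 and RT1-M5 were well above background in 1 of 6 rats and Or1p1e in 2. Olr1530 (now Or5ac23; adjusted p = 0.0187), the taste receptor Tas2r125 (adjusted p = 0.0274) and Slc7a11, the cystine importer (adjusted p = 0.0405), were higher without an exact size. The lipogenic genes Acly (1.14, adjusted p = 0.0953) and Fasn (1.29, adjusted p = 0.176) did not pass.

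Fatty acid oxidation genes were lower as a group in this comparison (29 of 31, median -0.28, adjusted p = 1.5e-09; adjusted p = 0.237 with an estimated correlation), though with slide as a block the median was -0.19 and the test against other genes turned to higher (adjusted p = 0.971). Iron and heme genes were lower too (16 of 21, median -0.12, adjusted p = 0.00503; adjusted p = 0.139 with an estimated correlation). Red blood cell genes were higher (11 of 11, median 0.999, adjusted p = 0.0217; adjusted p = 0.621 with an estimated correlation). None of the 7 lists called in this comparison was called in the same direction with slide as a block (0 of 7), where the medians were -0.23 for iron and 0.86 for red cell genes. In all 328 genes passed with limma (321 higher, 7 lower; 3181 at an unadjusted p under 0.05), and 0 with slide as a block. With quantile normalization 4 passed, and none of the genes named here did.

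The count for this last comparison depended on single rats. On low copper with 30% sucrose, 0 genes passed without rat 1 or without rat 2, 34 without rat 3, 797 without rat 4, 35 without rat 5 and 799 without rat 6. On the control diet 92 passed without rat 1, 140 without rat 2, 25 without rat 3, 0 without rat 4 and 0 without rat 6. On low copper with 10% sucrose, whose rats enter through the pooled spread, 632 passed without rat 3, 622 without rat 5 and 986 without rat 6, and on adequate copper with 30% sucrose 202 without rat 4. Mt1a kept values of -1.96 to -1.66 with adjusted p of 0.0193 to 0.110, and lost its call without rat 1, 2, 3 or 5 of its own diet or without rat 1, 2, 3, 4 or 6 of the control diet. Each of the other named genes above lost its call without 1 rat or more.

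Signal level went with the direction of the differences. In the dimmest of 5 equal groups of genes the median difference between low copper with 10% sucrose and the control diet was 0.62, and in the brightest group -0.03. With slide as a block the medians were 0.19 and -0.01. Of the dimmest group 1436 genes were called higher, and of the brightest 16. Among 390 odorant, vomeronasal and taste receptor genes, not known for use in liver, the median was 1.02 and 296 (75.9%) were called higher, 0 lower. The first principal component held 33.2% of the variance and averaged 46.1 on the control diet, 19.4 in the 2 rats on low copper with 10% sucrose that shared its slide, and -46.0 in the 4 on slide 2.

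**Figure D3:**
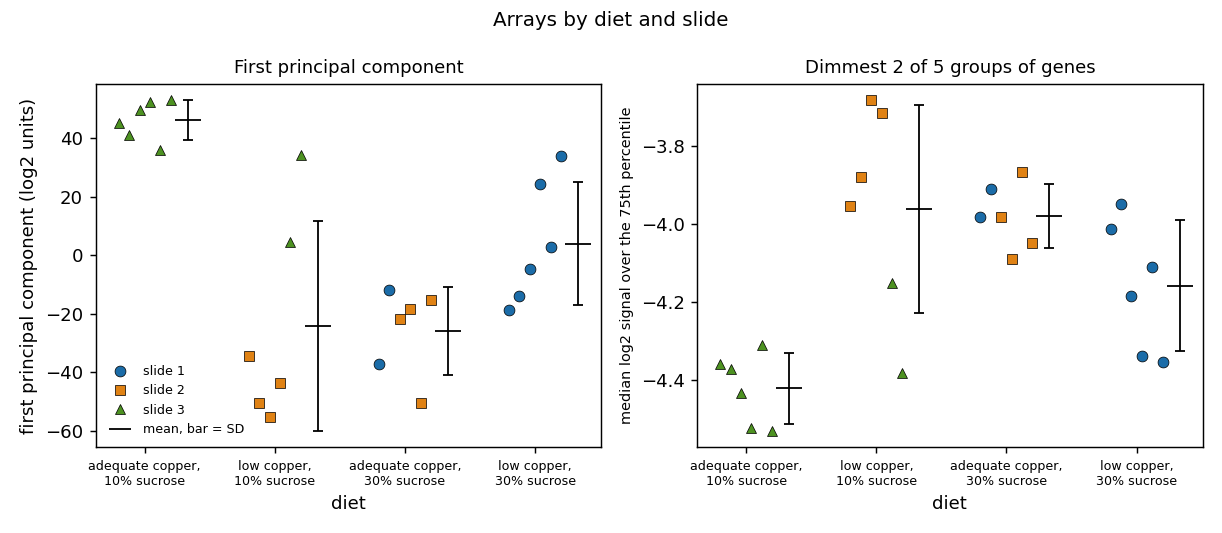
First principal component (log2 units) and median level of the dimmest 2 of 5 groups of genes (log2 signal over the 75th percentile), y axes, for each array by diet (x axis), with the mean and SD of each diet and a colour and shape per slide. Control rats averaged 46.1 on the component, and the 4 rats on low copper with 10% sucrose on slide 2 averaged -46.0.

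**Figure D4:**
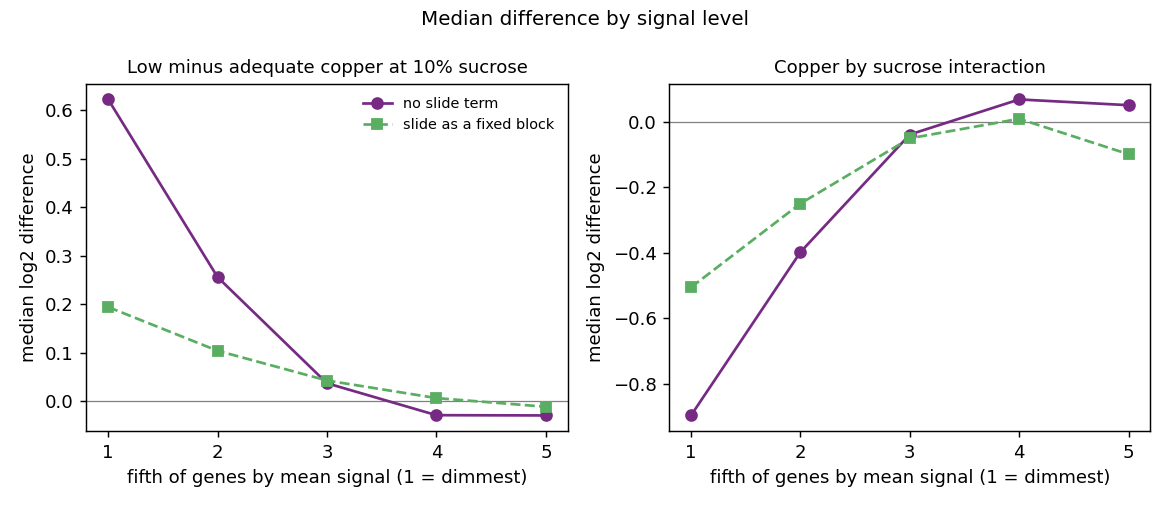
Median log2 difference (y axis) in each of 5 equal groups of genes by mean signal (x axis, 1 the dimmest), without a slide term and with slide as a fixed block. For low copper against adequate copper at 10% sucrose the dimmest group had a median of 0.62 without and 0.19 with the block.

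Across genes, the copper difference at 10% sucrose and that at 30% sucrose were opposed, with Pearson r = -0.59 and Spearman rho = -0.65 (r = -0.32 with slide as a block). The sucrose differences at adequate and at low copper gave r = -0.55 and rho = -0.57 (r = 0.26 with slide as a block). With the block both sucrose differences contain the same difference between the diets on slide 2. That sharing alone pushes r upwards, so the 0.26 does not show alike sucrose effects. Slide 2 holds 4 rats on low copper with 10% sucrose and 4 on adequate copper with 30% sucrose. A slide 2 effect would therefore enter the paired differences with opposite signs and make them look opposed, so the values without a block do not show opposed diet effects. Genes are not independent replicates, so no p is given. The differences of low copper with 10% sucrose and of adequate copper with 30% sucrose from the control diet share their control rats, and gave r = 0.92 across genes, against 0.50 in simulated data with that sharing alone. With the control rats divided between both differences r was 0.75 or 0.76. Neither value allows for slides. All 6 control rats lie on slide 3, and 4 of 6 rats of each of the 2 diets set against them lie on slide 2. A difference between these slides would enter both and would remain with the controls divided. The likeness alone therefore does not show a shared effect of the diets. In all 2846 genes were higher in both, and the 3 receptors Or1p1e, V1rd15 and Vom1r21 lay above the control mean in 6 of 6 rats in each.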

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

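Single rats stood apart from the other 5 of their diet in 42 of 432 tests of a gene in a group, where chance marks about 1 in 20 groups and so 21.6 were to be looked for. A rat was marked when the gap to its nearest neighbour, taken over the range of the group, passed the critical value for 6 rats (Dixon test). None of 24 tests on array values (0) marked a rat. Rat 2 of low copper with 10% sucrose was marked in 9 genes and rat 5 of adequate copper with 30% sucrose in 7.

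Rat 5 of adequate copper with 30% sucrose stood apart for Mt1a (8.25), Mt2A (7.18), Cp (8.50), Usp18 (-4.11), Ahsp (0.14), Lbp (4.69) and Il1rn (3.0). In rat 2 of low copper with 10% sucrose the marked genes were Cp (8.23), Steap4 (3.14), Hamp (6.02), Baat (6.18), Gde1 (1.38), Cox6c-ps1 (-3.84), Stac3 (-1.86), Lgsn (-6.73) and Hal (3.86). Others of low copper with 10% sucrose were rat 1 for Rtn1 (-3.97) and rat 6 for Gpr112l (-5.87), Acta2 (-2.27) and Trpv4 (-3.88). On adequate copper with 30% sucrose rat 1 was marked for Atp7a (-3.79), Fasn (6.46), Pex26 (-6.68) and Tcf21 (-4.93), rat 2 for Or52r1 (-6.12), rat 4 for Dolpp1 (-4.27) and rat 6 for Hba-a1 (5.43).

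On the control diet rat 1 stood apart for Oas1a (-3.72) and Usp18 (-4.05), rat 4 for Scd (8.51) and Lox (-5.86), rat 5 for Foxd3 (-4.84) and rat 6 for Steap4 (1.33) and Lbp (2.11). On low copper with 30% sucrose rat 1 stood apart for Steap4 (0.61) and Rtn1 (-5.45), rat 3 for Slc23a3 (-2.31), Lck (-4.24) and Arhgap23 (-3.19), rat 4 for Cxcl1 (3.26) and Cox6c-ps1 (-2.55), and rat 5 for Nox4 (-1.15). No array value set these rats apart.

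The interaction of copper and sucrose passed in 3884 genes without a slide term but in 10 with slide as a block, and named genes were marked when they passed without it. Negative were Cxcl1 (-4.76), S100a8 (-3.83), Vom1r21 (-3.69), S100a9 (-3.64), Cxcr2 (-2.80), Lbp (-1.91), Sqle (-1.64), Csf3r (-1.57), Lck (-1.52), Cd3d (-1.38), Cd8b (-1.11) and Socs3 (-1.01). Positive were Nox4 (1.98), Cox6c-ps1 (1.60), Ripk4 (1.47), Acot12 (0.81) and Rgn (0.71). The negative values with slide as a block were, in the same order, -4.51, -1.63, -2.16, -1.74, -1.48, -1.20, -1.14, -0.64, -0.96, -0.95, -0.84 and -0.56, and the positive ones 0.71, 0.44, 0.84, 0.765 and 0.80. With normexp Ripk4 stood at 0.0346 (adjusted p = 0.933), Nox4 at 1.06 and Vom1r21 at -1.35. Nox4 lost its call without 1 of 9 rats: rats 5 and 6 of low copper with 30% sucrose, rat 6 of adequate copper with 30% sucrose, rats 1, 2 and 5 of low copper with 10% sucrose and rats 1, 2 and 3 of the control diet. Lbp lost it without rat 1, 3 or 4 of the control diet, rat 5 of adequate copper with 30% sucrose, or rat 5 or 6 of low copper with 30% sucrose (adjusted p up to 0.0608), and Sqle without any 1 of 14 rats (up to 0.0751). Without rat 5 of adequate copper with 30% sucrose and rat 2 of low copper with 10% sucrose the calls of Cxcl1 (-3.76, adjusted p = 0.0839), Sqle (-1.11, 0.110), Nox4 (1.17, 0.0643) and Ripk4 (1.23, 0.0602) were lost, and S100a8 (-2.27), S100a9 (-2.16), Lbp (-1.08) and Cox6c-ps1 (0.98) shrank. Col6a3, Rrm2b and Hist1h3f were marked too, but each was well above background in 0 of 6 rats of a diet, so the fitted values of -3.71, 1.68 and 1.49 do not measure a size. Over the alternatives they ran from -4.01 to -0.997, from -0.0177 to 2.42 and from 0.15 to 2.37. The lists marked had medians of 0.24 for fatty acid and triglyceride synthesis, 0.20 for fructose and glucose, 0.21 for fatty acid oxidation, 0.32 for bile acids, 0.46 for drug metabolism, -0.93 for inflammatory genes, -0.96 for T, B and NK cells, -1.56 for neutrophils, 0.13 for hepatocytes, 0.34 for oxidative stress and 0.27 for the respiratory chain. Under the slide block these medians were -0.22, -0.05, 0.20, 0.15, 0.38, -0.46, -0.16, -0.95, 0.06, 0.12 and 0.04. None of these 11 calls held with an estimated correlation, and without the same pair of rats those of fatty acid oxidation (0.03, adjusted p = 0.0686) and of inflammatory genes (-0.64, adjusted p = 0.0786) were lost.

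Of the tests of the first pattern, many mostly dim genes higher on low copper with 10% sucrose than on the control diet, those of slide, of diet within slide 3 and of normalization were chosen only after the result was seen. Within low copper with 10% sucrose the called genes lay 0.736 higher on slide 2 than on slide 3, and the highest of the other divisions of these rats gave 0.398. That difference is 0.762 of their median change of 0.97 against the control diet, past the bound written for a slide difference. Only 4 of the 6 rats lie on slide 2, so it enters the change in part only. With slide as a block a median of 0.43 was left, for genes chosen on the same rats without a block. A slide difference may therefore account for part of the pattern, and how large a part was not settled. Within slide 3 the dim genes lay 0.154 higher in the 2 low copper rats, with an exact two-sided permutation p of 0.179 (smallest possible 0.0357), which leaves a diet effect open. After quantile normalization 0.498 of the called genes were still called, between both bounds written for that test, so a curve in the normalization could not be told apart. Receptor genes not known for use in liver lay 0.595 above genes of matched brightness (range -0.0979 to 0.0904 over 10000 draws), a side that neither written bound had named, and the reading that brightness alone is not enough was made after that value was seen.

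For the second pattern, lower Mt1a and Mt2A on low copper, no test was chosen after the result was seen. The within-slide difference nearest to 0 was -0.737, on slide 1, and that on slide 3 was -1.77, both past the bound written beforehand against a slide difference. The exact two-sided permutation p for the mean of both genes was 0.00128, the smallest possible. Lower copper in the diet is one hypothesis that is consistent with this value of 0.00128, and the food intake of the rats was not open to test.

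Regrouping the rats, planned beforehand, asked whether other divisions give as many genes, over 100 divisions per comparison with the real one included. For the interaction 1 division, the real one, gave as many genes (3884, highest other 152). The real one alone also did so for low copper at 10% sucrose (3469, highest other 964), 30% sucrose at adequate copper (3888, highest other 2) and both changes against the control diet (328, highest other 14). These divisions mix rats across slides, while each real diet lies mostly on 1 slide. A slide difference alone could therefore also set the real division apart, so the test does not tell diet from slide. With slide as a block the counts were 10, 0, 0 and 0. For mean copper (highest other 15), mean sucrose (highest other 2713), low copper at 30% sucrose (highest other 88) and 30% sucrose at low copper (highest other 1689) the real count was 0, so all 100 divisions had to give as many, and the test says nothing about chance there. The 2713 and the 1689 point to a structure of the samples. The first set all 8 arrays of slide 2 on 1 side, and the second set 4 arrays of slide 1 and 2 of slide 3 against 2 of slide 1 and 4 of slide 2. The 964 set 6 rats of slide 3 against 4 of slide 2 and 2 of slide 3.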

How the results depend on the processing

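Signal was weak for many genes, with a background of 38 to 48 against a 75th percentile of 433 to 1284, and slides and diets overlapped, so slide-blocked values carry wide errors. The cause of the changes below was not tested. Counts are in the order interaction, low copper at 10% sucrose, 30% sucrose at adequate copper, and both changes against the control diet, unless named. With normexp the last 3 became 2056, 2342 and 0, and Rrm2b, at background in all rats of a diet, reversed in the interaction (-0.0177). Quantile normalization gave 2572, 2058, 2507 and 4, and the filter on all arrays 2294, 1866, 2267 and 10. The authors' table, put back on an assumed signal scale, gave 2393, 1950, 2463 and 2 with 1 for mean copper. No filter gave 75 for both changes, the replicate block 639, only both groups compared 986, and array weights 2126, with 875 for mean copper. The lowest array weight fell on rat 6 of low copper with 10% sucrose, on slide 3, so the weighted counts also reflect a closer tie of diet to slide. With fry 4 lists were called in the interaction, 1 for low copper at 10% sucrose and 2 for 30% sucrose at adequate copper. In each of the other comparisons fry called 0 lists.

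The slide block gave 10, 0, 0 and 0, with 20 for low copper at 30% sucrose and 6 for 30% sucrose at low copper, and moved the likeness of both copper differences to -0.32 and reversed that of both sucrose differences to 0.26. It reversed Lama1 for 30% sucrose at adequate copper (-0.0571), and for both changes Csf3r (-0.0256), Lipe (-0.31), Rph3a (-0.67), Spink5 (-0.37), Sypl2 (-0.93), Tcte1 (-0.56) and V1rd15 (-0.0417). Lists that reversed against other genes under the slide block, with or without an estimated correlation, had these medians: inflammatory 0.0262 with mean copper; fatty acid oxidation -0.11 and bile acids -0.0815 with mean sucrose; T, B and NK cells -0.13 with low copper at 10% sucrose and -0.29 with 30% sucrose at adequate copper. For low copper at 30% sucrose they were inflammatory -0.13 and fibrosis 0.13, for 30% sucrose at low copper fructose and glucose -0.25, neutrophils -0.18 and respiratory chain -0.13, and for both changes fatty acid oxidation -0.19 and bile acids -0.0579.

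Slide as a random block gave 1808, 2286, 1231 and 0, and slide position 576 for both changes and 1 for mean copper. Without slide 2 the counts were 0, 0, 1736 and 1015, with 952 for mean sucrose and 6 for low copper at 30% sucrose, and likenesses of -0.32 and 0.21. In that setting all rats on 30% sucrose lie on slide 1 and all on 10% sucrose on slide 3. The 1736, 1015 and 952 and the likeness of 0.21 thus cannot be told apart from a slide difference. Quantile normalization with the slide block gave 5, 0, 0 and 0, with 8 for low copper at 30% sucrose and 1 for 30% sucrose at low copper. Without the pair of rats that stood apart the counts were 2732, 2928, 3131 and 260.

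Leaving out each rat in turn gave 3054 to 4828, 2599 to 4264, 2933 to 4104 and 0 to 986, with 0 to 19 for mean copper (19 without rat 6 of low copper with 10% sucrose), 0 to 1 for mean sucrose (1 without rat 2 of that diet), 0 to 0 for low copper at 30% sucrose and 0 to 41 for 30% sucrose at low copper (41 without rat 6, 2 without rat 5 of the same diet). Rats 5 and 6 of low copper with 10% sucrose are the 2 of that diet on slide 3, so the counts without them also reflect a closer tie of diet to slide. The likenesses ran from -0.63 to -0.50 and from -0.63 to -0.42. Of 11496 gene results with 1 rat left out 0 reversed, and 273 became weaker. Only results that passed with all rats could be marked either way, so the share of 11496 does not measure how steady the calls were. Among genes of the text, the calls named by the rule that were kept without each rat were 9 of 10, 7 of 10, 6 of 11 and 0 of 20. Alternatives not run were other array scalings by spike-in controls and a model of weak signals.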

Other observations

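On low copper with 30% sucrose Mt2A varied little between rats (SD 0.14), while on adequate copper with 30% sucrose the SD of 1.66 came mostly from rat 5, at 7.18 with the next rat at 3.995. Hamp, which rises in inflammation, was at 7.12 on adequate copper with 30% sucrose and at 6.52 on low copper with 30% sucrose. Acly, which supplies acetyl groups for fat synthesis, was at 5.43 on low copper with 30% sucrose and at 4.29 on the control diet, beside Fasn at 5.26 and 3.97.

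The lower metallothionein genes within slides may reflect less copper in the liver, a hypothesis that rests on the exact two-sided permutation p of 0.00128, and copper measured in the same livers would test it. The inflammatory genes on adequate copper with 30% sucrose could reflect neutrophils in the tissue, though on the slide-blocked fit 0 genes passed in that comparison. Counting neutrophils in sections of the same livers would test this. The higher receptor genes on low copper with 10% sucrose, which lay 0.595 above genes of matched brightness, may come from labelling or hybridization, and a repeat of some livers across slides with diets mixed on each would test that.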
